A study of Mus musculus with 16 samples.

How the data were processed

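RNA bisulfite sequencing libraries were analysed from mouse embryonic stem cells, per the labels of the J1 background, grown on mouse embryonic fibroblast feeders that were then removed by letting them attach to dishes. Per the labels' protocols, total RNA was split at 200 nt into a small and a long fraction, the small fraction and part of the long fraction were depleted of rRNA, and the RNA was bisulfite treated and sequenced as paired ends. The groups, taken from the labels, are wild type and Dnmt2 knockout in each of 3 fractions: small (3 and 3 libraries), rRNA-depleted long (3 and 3) and undepleted long (2 and 2), 16 libraries in all. The labels do not say whether the replicates come from separate cultures or lines, so p-values measure only the spread between these samples, which may be technical.

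Per the file headers, each deposited file lists, for a cytosine of a reference RNA, the coverage (a count of reads, not normalized) and the unconversion ratio, a fraction from 0 to 1 of these reads that were not converted. Per the submitters' processing notes the authors used BSMAP and build mm9; the version and the filters are not given in the sources used here. The lowest coverage listed was 3, so an unlisted cytosine had fewer reads or was left out, and it was taken as 0 in coverage. In all 20853453 entries, 1 per cytosine and library, coverage times ratio lay within 3.8e-07 of a whole number (tolerance 0.01), so non-converted and converted read counts were recovered. Reads without molecular identifiers are not independent molecules. Reads of the small fraction were placed on 182 references to tRNA genes named with mm9 coordinates, 3 of which merge several genes; those of the rRNA-depleted long fraction on 15330 RefSeq mRNAs; and those of the undepleted long fraction on 5 references, namely 18S, 28S and 5.8S rRNA and 2 Ensembl transcripts given by identifier. Of the 15330 mRNAs, 15235 were matched to a gene symbol through a RefSeq gene table of another mouse assembly, GRCm38.p6, which was used for names, for the chromosome of a gene and for gene order, never for coordinates. Positions count from 1 at the 5′ end of the reference, so position 38 of tRNA-Gly-GCC is linear position 37.

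Before the data were examined, the tests, alternatives, gene lists and the rule for named genes were fixed. Genotypes were compared per cytosine with the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on non-converted and converted counts, with a term per library and the interaction of genotype with conversion state, at cytosines with coverage of 10 or more in every library and a mean non-conversion of 5% or more. Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout. Within a genotype a cytosine was called methylated from 1-sided exact binomial tests against each library's background, combined by Fisher's method and adjusted, with coverage of 10 or more and non-conversion of 10% or more in every library. The background of a library was its pooled non-conversion over cytosines at coverage of 10 or more and non-conversion of 10% or less. Position 38 and the background were compared with exact permutation tests, two-sided, whose smallest p is 0.1 for 3 against 3 libraries and 0.333 for 2 against 2.

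Coverage of a transcript was the mean over the cytosines listed in any library, which counts a read once per cytosine and is not a read count. It was scaled by TMM factors, filtered at a mean of 1 or more, and tested with limma 3.58.1 (trend) on log2 of the value plus a pseudocount of 0.5, a scale that understates changes of low transcripts. Log2 differences are on this scale, knockout minus wild type. Lists were tested with camera, with the preset correlation of 0.01 and with an estimated one, and adjusted over 8 lists. The lists were pluripotency, feeder fibroblasts, early lineages, RNA and DNA cytosine methylation, aminoacyl-tRNA synthetases, the integrated stress response, imprinted genes, structural noncoding RNAs and mitochondrial transcripts, and for tRNA cytosines the substrates of Dnmt2, Nsun2 and Nsun6. Substrates of Nsun3 and 5S rRNA were not analysed here. Some well-covered transcripts are unlisted in single libraries: of those with 100 or more cytosines and a mean coverage of 5 or more in the libraries that list them, 11 have no listed cytosine in at least 1 library, for example Hsp90ab1 (528 to 1454 in 5 libraries, with no listed cytosine in wild type replicate 2). They entered the test at a coverage of 0 in such a library, and a fit without these transcripts was added.

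Depth sets the precision: per library the summed coverage was 25431862 to 55009793 (small), 37786723 to 143488903 (rRNA-depleted long) and 35668553 to 40163061 (undepleted long), and the median coverage of a listed cytosine was 96 to 171, 6 to 11 and 3769 to 4156 reads. In no pair of libraries of a group did more than 1.17% of the cytosines have identical values, and every pair differed by more than the counting error of independent reads (chi-square of the counts over its degrees of freedom 1.89 or more), a ratio that PCR copies can also raise. Replicate 3 of both genotypes stood apart: replicates 1 and 2 gave ratios of 70.3 (wild type) and 135 (knockout) in the small fraction, against 1366 to 2489 for pairs with replicate 3. In the rRNA-depleted long fraction these were 4.07 and 1.89, against 8.02 to 11.6. The replicate numbers come from the sample titles. The correlation of deviations between same-numbered libraries was 0.334, 0.315 and 0.649 for tRNA cytosines, 0.239, 0.109 and 0.391 for mRNA cytosines and 0.503, 0.491 and 0.719 for tRNA coverage, all over 0.1, the criterion under which the numbers were taken to pair those libraries, and fits with the number as a block were run beside the others. Not every library correlated highest with its own number: wild type replicate 1 and knockout replicate 2 gave 0.346 and wild type replicate 2 and knockout replicate 1 gave 0.343 for tRNA cytosines, and the latter pair gave 0.691 for tRNA coverage. Deviations were taken from the mean of 3 libraries, so a replicate 3 that stands apart can by itself make replicates 1 and 2 correlate. The values thus set replicate 3 apart and do not show that the numbers 1 and 2 pair libraries.

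Named genes were chosen by the fixed rule: Trdmt1 first; per comparison up to 10 cytosines that fell and 10 that rose the most among those past the threshold, 1 per RNA family first; per fraction the 10 called cytosines highest in wild type, 1 per family first; up to 10 transcripts each way in coverage; and of each list up to 4 members past the threshold or, with none, the 2 of highest coverage. Others are said to be chosen after their values were seen. The alternatives were coverage minimums of 5 and 30, a mean non-conversion of 1% or more, a call minimum of 20%, the background from the share of cytosines without a non-converted read, Fisher's exact test on summed counts, scaling by total coverage or the median of ratios, a mean coverage of 10 or more or no filter, a pseudocount of 0.1, the replicate block and each library left out. After the data were seen, fits without both replicate 3 libraries, with library quality weights, without the unlisted transcripts and on cytosines covered in all 6 libraries were added.

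The steps were tested on simulated data with known changes. For cytosines these were falls only, from levels raised to 30% or more, with a simulated SD between libraries of 0.3 on the logit scale. Over 265 tRNA cytosines 15 of 20 changes of log2 odds 2 and 20 of 20 of log2 odds 5 were recovered with 0 false calls; over 8186 mRNA cytosines 20 of 100 and 85 of 100 with 1 false call; over 162 cytosines of the undepleted fraction 16 of 20 at both sizes with 1 false call. For coverage, 25 of 100 changes of log2 1 and 68 of 100 of log2 2 were recovered over 10949 transcripts with 6 false calls, and 7 of 20 and 15 of 20 over 174 tRNA genes with 0. Calls recovered 199, 194 and 200 of 200 cytosines set to 30% in the small, rRNA-depleted and undepleted fractions, with 0 false calls. All other cytosines were drawn at the background rate of the library, without spread between sites. The 0 therefore says nothing about false calls where conversion is locally incomplete. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.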

Results

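RNA bisulfite sequencing was analysed in mouse embryonic stem cells of the J1 background that were wild type or lacked Dnmt2, a tRNA cytosine methyltransferase whose gene symbol is Trdmt1. Bisulfite turns unmethylated cytosines into uracil and leaves 5-methylcytosine as cytosine, so non-conversion, the percentage of reads that still carried a cytosine, was taken as the methylation level of a site. Of 16 libraries, 6 held the small RNA fraction, 6 the rRNA-depleted long fraction and 4 the undepleted long fraction, with 3, 3 and 2 libraries per genotype. The small libraries listed 2886 to 3298 cytosines of tRNA genes, at a summed coverage of 25431862 to 55009793 reads over cytosines. The rRNA-depleted long libraries listed 2304342 cytosines (wild type replicate 3, summed coverage 37786723) to 4289381 cytosines (wild type replicate 2, 143488903) of mRNAs. The undepleted long libraries listed 2480 to 2484 cytosines at a summed coverage of 35668553 to 40163061.

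The transcript of the targeted gene, Trdmt1 (NM_010067.4), was examined first. In wild type replicates 1, 2 and 3, 95, 127 and 48 of its 154 cytosines from transcript position 200 onward were listed, against 0, 0 and 0 in the 3 knockout replicates. Upstream of that position the knockout replicates listed 32, 16 and 32 cytosines, the last of them at positions 142, 84 and 142, and the wild-type replicates listed 32, 32 and 15. Mean coverage from position 200 was 3.18 ± 1.92 (SD, n = 3) in wild type, and no cytosine was listed there in a knockout library, which was taken as 0 (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries allow). The scaled mean coverage of the whole transcript was 4.32, 3.47 and 2.91 in wild type and 1.30, 0.462 and 0.976 in the knockout. Position 200 was chosen after the values were seen.

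**Figure D1:**
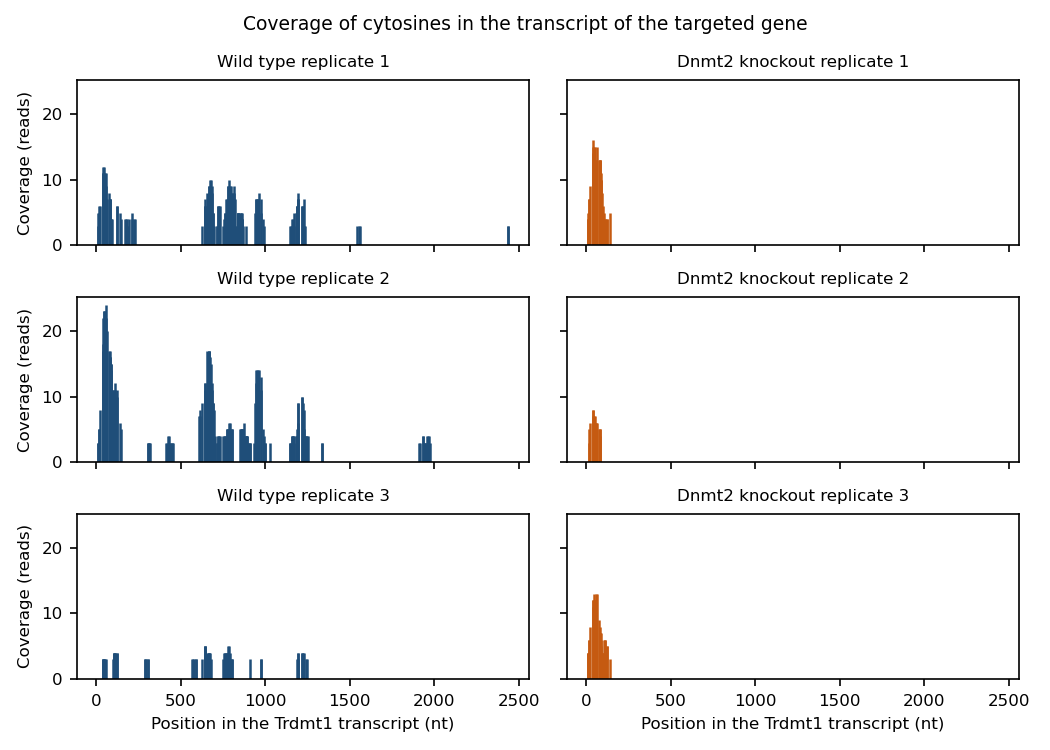
Coverage (reads, vertical axis) of each cytosine of the Trdmt1 transcript against its position in the transcript (nt, horizontal axis), 1 panel per rRNA-depleted long library, a cytosine that was not listed drawn at 0. From position 200 onward, 48 to 127 cytosines were listed in a wild-type library and 0 in a knockout library.

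To find which tRNA cytosines depend on Dnmt2, non-conversion was compared between genotypes at 265 cytosines of the small fraction. At position 38 of the anticodon loop of the 3 textbook Dnmt2 substrates, non-conversion was high in wild type and low in the knockout. The knockout values lay above the background of these libraries, 1.97% ± 0.164 (SD, n = 3). Pooled over gene copies it was 91.8% ± 1.44 (SD, n = 3) in wild type and 3.13% ± 0.081 in the knockout for tRNA-Asp-GTC, 81.7% ± 0.534 and 4.03% ± 0.322 for tRNA-Gly-GCC, and 87.7% ± 1.48 and 2.44% ± 0.699 for tRNA-Val-AAC. Together the 3 tRNAs stood at 90.4% ± 1.26 and 3.23% ± 0.1, a difference of -87.2 percentage points (exact permutation test, two-sided p = 0.1, the smallest possible). In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 14 of the 265 cytosines fell in the knockout and 0 rose, and 34 had an unadjusted p under 0.05. Of the 14, 10 were position 38 of the 3 substrates, which are all 10 of the copies tested, and 10 fell when adjusted over the list alone. With the replicate number as a block, 27 cytosines passed (23 lower, 4 higher), including all of the 14. The p-values of that fit are too small to measure the spread of 3 pairs of libraries, so the calls it added are uncertain.

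Among the copies, the cytosine fell from 91.8% ± 1.45 to 3.11% ± 0.085 (SD, n = 3) in tRNA-Asp-GTC (chr10.trna851; mm9 chromosome 10, 92915723 to 92915794, minus strand), at 383389 reads or more per library and an edgeR adjusted p of 1.14e-09. In tRNA-Asp-GTC (chr10.trna856; chromosome 10, 90644842 to 90644913, minus strand) it fell from 91.8% ± 1.35 to 3.28% ± 0.081. In tRNA-Gly-GCC (chr11.trna1819; chromosome 11, 68932296 to 68932366, minus strand) it lies at linear position 37 and fell from 91.8% ± 1.18 to 4.39% ± 0.14, and in the copy on chromosome 1 (chr1.trna702; 172996762 to 172996832, plus strand) from 70.7% ± 1.51 to 3.77% ± 0.649. In tRNA-Val-AAC (chr13.trna974; chromosome 13, 22107660 to 22107732, minus strand) it fell from 93.3% ± 0.551 to 2.80% ± 0.84 (edgeR adjusted p = 3.22e-09), and in chr13.trna95 (23390650 to 23390722, plus strand) from 66.9% ± 0.485 to 1.56% ± 0.25. The tRNA-Asp-GTC copy on chromosome 2 (chr2.trna510, 27 reads or more) fell from 92.6% ± 2.33 to 9.22% ± 4.85. The tRNA-Val-AAC copy on chromosome 11 (chr11.trna208), covered by 37 reads or more, was low in both genotypes, at 3.70% ± 1.62 and 0% in each knockout library. The tRNA-Val-AAC copies chr13.trna93 and chr13.trna965, at 8 and 9 reads or more, were also low in wild type (2.08% ± 3.61 and 3.09% ± 2.83). Near-identical gene copies can share reads, so the assignment of a value to a single copy is uncertain.

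**Figure D2:**
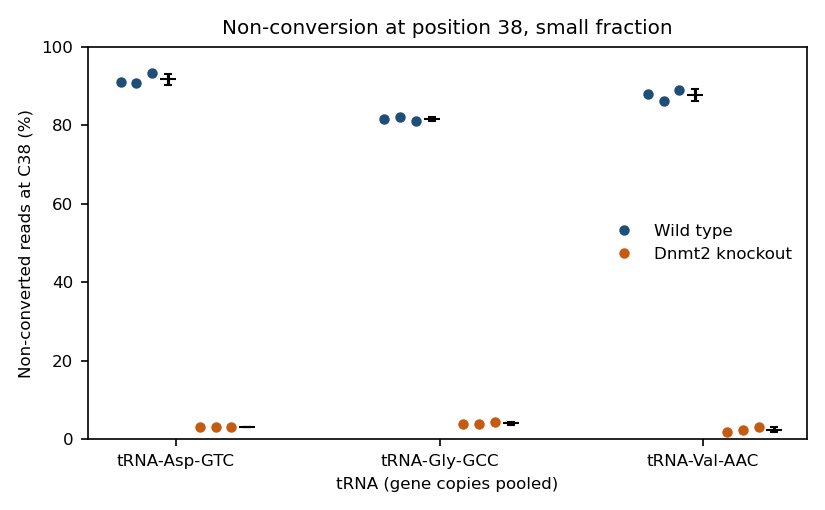
Non-conversion (percent, vertical axis) at position 38, reads pooled over gene copies, for tRNA-Asp-GTC, tRNA-Gly-GCC and tRNA-Val-AAC in wild type and knockout, with points for single libraries and bars for mean and SD. Wild-type means lie at 81.7% to 91.8% and knockout means at 2.44% to 4.03%.

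The other 4 cytosines that fell lay outside that list. In tRNA-Val-CAC (chr13.trna964; mm9 chromosome 13, 23503946 to 23504018, minus strand), the cytosine at linear position 38 fell from 38.9% ± 4.24 to 1.85% ± 2.12 (SD, n = 3; edgeR adjusted p = 0.00019; 59 reads or more). In a tRNA-Gly-GCC copy (chr4.trna1314), the next cytosine, at linear position 38, fell from 8.75% ± 1.34 to 1.86% ± 0.615 (edgeR adjusted p = 0.000438). In tRNA-Ala-TGC (chr13.trna68), linear position 39 fell from 58.3% ± 1.35 to 38.9% ± 3.69 (edgeR adjusted p = 0.0332). In tRNA-Gly-CCC (chr3.trna752; chromosome 3, 96227956 to 96228026, minus strand), position 47 of the variable loop fell from 94.0% ± 1.23 to 87.5% ± 3.11 (edgeR adjusted p = 0.0319). The tRNA-Ala-TGC call was lost without wild type replicates 1, 2 or 3 or knockout replicates 1 or 2 (edgeR adjusted p = 0.217, 0.136, 0.0854, 0.135 and 0.138) and at a mean non-conversion of 1% or more (edgeR adjusted p = 0.111). The chr4.trna1314 cytosine was not tested without wild type replicates 1, 2 or 3, since its mean non-conversion then lay under the minimum of 5%. The tRNA-Gly-CCC call was lost without wild type replicates 1 or 2 or knockout replicate 1 (edgeR adjusted p = 0.212, 0.152 and 0.167).

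Cytosines that other tRNA methyltransferases modify were compared as lists fixed in advance. The wobble cytosine of tRNA-Leu-CAA, a substrate of Nsun2, was called methylated in all 4 copies in both genotypes. It stood at 72.5% ± 0.258 and 81.7% ± 4.50 (SD, n = 3) in chr13.trna65 (edgeR adjusted p = 0.352) and at 86.7% ± 3.06 and 86.1% ± 5.31 in chr11.trna1911 (edgeR adjusted p = 0.961). The variable-loop list, also attributed to Nsun2, took every cytosine in a window of linear positions, with tRNA-Leu, tRNA-Ser and tRNA-Tyr left out. It can thus hold cytosines outside that loop. Of this list 190 were covered in every library, and 113 were called in wild type and 129 in the knockout. Calls need coverage in 1 genotype only, and over all tRNA cytosines 16 knockout calls were not tested in wild type. Of the 133 tested there, 1 fell (the tRNA-Gly-CCC site above), 0 fell when adjusted over the list alone, and 9 fell and 1 rose with the replicate block. At the acceptor-stem cytosines of Nsun6 substrates, 7 of 17 were called in both genotypes, for example tRNA-Thr-CGT (chr11.trna550) at 82.8% ± 1.69 and 81.1% ± 2.16 and tRNA-Thr-TGT (chr14.trna190) at 91.6% ± 1.30 and 89.8% ± 3.00 (edgeR adjusted p = 0.836 for both). In the edgeR test, 0 of these 7 and 0 of the 4 wobble cytosines passed, over all cytosines and when adjusted over the list alone; 1 acceptor-stem cytosine rose with the replicate block.

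**Figure D3:**
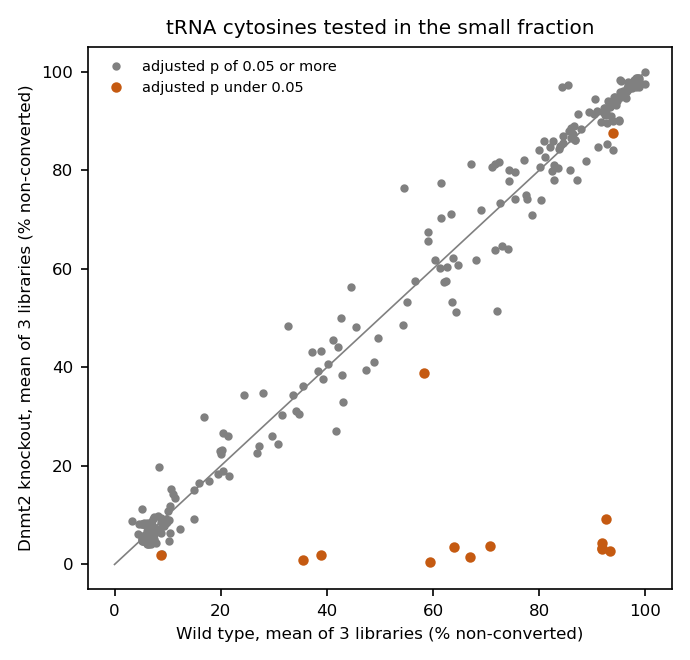
Mean non-conversion in the knockout (percent, vertical axis) against wild type (percent, horizontal axis) for the tRNA cytosines tested in the small fraction, 1 point per cytosine, the 14 cytosines with an edgeR adjusted p under 0.05 in orange, the others in grey and the line of equal values drawn. Of the 14, the 10 substrate cytosines lie at knockout values of 0.433% to 9.22%, far below the line.

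Taken for each genotype on its own, 189 of 2395 tRNA cytosines were called methylated in wild type and 196 of 2650 in the knockout, with 176 called in both. The sites highest in wild type included tRNA-Glu-TTC (chr13.trna105; mm9 chromosome 13, 23555404 to 23555475) position 48 at 98.8% ± 0.038 (SD, n = 3; 199063 reads or more) and 98.7% ± 0.197 in the knockout. The others were tRNA-Val-TAC (chr19.trna109) position 48 at 98.7% ± 0.149, tRNA-Lys-CTT (chr11.trna2023) position 48 at 98.5% ± 0.233, tRNA-Gly-GCC (chr1.trna702) position 47 at 98.3% ± 0.113 and tRNA-Asp-GTC (chr10.trna856) position 48 at 98.0% ± 0.286. In the knockout these stood at 98.7% ± 0.284, 98.6% ± 0.109, 98.0% ± 0.926 and 98.2% ± 0.069. Fewer reads lay behind tRNA-Ile-TAT (chr1.trna583) position 49 at 100% in each wild-type library (10 to 48 reads), tRNA-Ala-CGC (chrX.trna369) position 58 at 100% (12 to 15 reads), tRNA-Ala-TGC (chrX.trna363) position 48 at 98.8% ± 0.419, tRNA-Ile-GAT (chr2.trna1506) position 49 at 98.8% ± 1.48 and tRNA-Ser-GCT (chr1.trna791) position 57 at 98.2% ± 0.827.

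In mRNAs, single cytosines stood far above background in both genotypes. Non-conversion was 74.7% ± 11.4 (SD, n = 3) in wild type and 74.3% ± 1.09 in the knockout at position 521 of Nid2 (NM_008695.2), which encodes the basement membrane protein nidogen 2, at 38 reads or more in wild type. It was 72.1% ± 2.42 and 75.5% ± 3.92 at position 680 of Cenpv, 66.6% ± 4.97 and 64.9% ± 2.67 at position 2857 of Sec61a1, a subunit of the endoplasmic reticulum translocon, and 58.6% ± 3.21 and 65.8% ± 0.927 at position 473 of Nus1. These are among the 10 named sites highest in wild type, 1 per transcript first. The others were position 421 of the histone gene H3c6 (100% in each wild-type library and 94.8% ± 4.82 in the knockout), position 153 of Rpl34-ps1 (94.6% ± 2.22 and 90.2% ± 5.25), 3097 of Nkd2 (92.4% ± 6.61 and 95.6% ± 4.72), 171 of H2ac20 (88.3% ± 2.13 and 87.0% ± 0.046), 703 of Rps2 (86.5% ± 9.68 and 93.7% ± 5.55) and 362 of Rab4b (64.1% ± 8.80 and 63.3% ± 8.67). Histone, ribosomal protein and pseudogene sequences have near-identical copies elsewhere in the genome, so the copy behind H3c6, H2ac20, Rps2 and Rpl34-ps1 is uncertain. Positions count from the start of the RefSeq transcript, and whether a site lies in coding sequence or UTR was not analysed here.

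Of 8186 mRNA cytosines tested, 0 differed between genotypes in the edgeR test, where 201 had an unadjusted p under 0.05. With the replicate block 0 passed, and Fisher's exact test on summed counts, which ignores the spread between libraries, called 27 (26 higher and 1 lower in the knockout). Without wild type replicate 3, the shallowest library, 1 of 22058 passed: position 307 of Rad23b, 19.4 percentage points higher in the knockout (edgeR adjusted p = 0.0023). In simulated data the test recovered 20 of 100 falls of log2 odds 2 and 85 of 100 of log2 odds 5 at this size. Smaller differences were thus often not detectable at this depth. The simulated falls started from levels of 30% or more, so recovery at sites of lower level was not measured.

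Called on its own, each genotype gave 162 methylated cytosines in 119 transcripts (wild type, 765735 tested) and 387 in 259 transcripts (knockout, 1365927 tested). Among the 741725 cytosines tested in both, 118 were called in both, 40 in wild type and not in the knockout, and 111 in the knockout and not in wild type. For these cytosines, whether a site called in 1 genotype differs is what the test above measured. It could not measure the 158 knockout calls and 4 wild-type calls at cytosines not tested in the other genotype. Transcripts with the most calls in wild type were Trim71 (14 in wild type, 25 in the knockout), which encodes an RNA-binding ubiquitin ligase of stem cells, Cep170b (5 and 4), Polr2f (5 and 3) and Tnks2 (4 and 11). Those with the most calls in the knockout were Trim71, Ppp1r14b (2 in wild type, 17 in the knockout), Tnks2, Mycn (1 and 9) and Sap30l (0 and 9). All of these were chosen after their values were seen. Without wild type replicate 3 the wild-type count was 357, and without both replicate 3 libraries the counts were 357 and 578.

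In the undepleted long fraction, 19 of 2461 cytosines were called in wild type and 17 of 2469 in the knockout, 10 of them in both. The references were 18S, 28S and 5.8S rRNA and 2 Ensembl transcripts whose identity was not looked up, so they may also be rRNA. On 28S rRNA, position 3438 stood at 96.4% ± 0.729 (SD, n = 2) and 97.0% ± 0.63 in the knockout, and position 4099 at 95.7% ± 0.035 and 95.8% ± 0.187, each at 1333 reads or more. In the transcript ENSMUST00000082388, given by its identifier, position 842 stood at 81.5% ± 2.26 and 81.6% ± 1.66 and position 840 at 49.7% ± 3.22 and 55.2% ± 1.39. The other sites called in wild type stood there at 20.8% or lower. Those named by the rule were 28S positions 2951 (20.8% ± 5.89 and 15.3% ± 8.72 in the knockout), 4473 (17.5% ± 3.42 and 15.6% ± 1.83), 2877 (17.4% ± 1.07 and 16.3% ± 7.30), 1229 (16.6% ± 0.556 and 17.3% ± 1.93) and 4475 (14.8% ± 1.01 and 13.2% ± 1.22), and position 726 of ENSMUST00000082390 (13.3% ± 2.21 and 7.23% ± 1.10). Of these, position 2951 and position 726 were not called in the knockout. Positions 2951 and 2877 had only 11 to 12 wild-type reads per library. Some of the low sites lay among other partly non-converted cytosines. In wild type, 28S position 1229 lay beside 1230 (13.8%) and 1231 (8.07%), and position 4473 near 4470 (12.3%) and 4475. Whether conversion was locally incomplete there was not tested.

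Of 162 cytosines tested in that fraction, 1 passed: position 2078 of 28S rRNA fell from 7.85% ± 0.3 to 5.71% ± 0.644 (SD, n = 2; edgeR adjusted p = 0.0316). The call was lost at a mean non-conversion of 1% or more (edgeR adjusted p = 0.46). It was also lost without wild type replicates 1 or 2 (edgeR adjusted p = 0.706 and 0.281) and without knockout replicates 1 or 2 (edgeR adjusted p = 0.666 and 0.624). These fits leave 1 library in an arm and assume that it varies like the other group. The difference at 28S rRNA position 2078 was then -1.68 to -2.59 percentage points, against -2.14.

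The background left by incomplete conversion was compared between genotypes in each fraction. In the small fraction it was 1.89% ± 0.155 (SD, n = 3) in wild type and 1.97% ± 0.164 in the knockout (exact permutation test, two-sided p = 0.6). In the rRNA-depleted long fraction it was 1.51% ± 0.0722 and 1.65% ± 0.196 (exact permutation p = 0.4). There, where more cytosines were called in the knockout, the difference was 0.138 percentage points, and 0.251 without knockout replicate 3 (exact permutation p = 0.1, the smallest possible). In the undepleted fraction it was 1.47% ± 0.116 and 1.41% ± 0.0355 (n = 2; exact permutation p = 0.667, where 0.333 is the smallest possible).

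Coverage per transcript served as a measure of mRNA level. Of the pluripotency list's 26 transcripts (23 genes), 6 were lower in the knockout and the others higher, with a median log2 difference of 0.26; 0 passed, over all transcripts or adjusted over the list alone. Dppa5a, a marker of naive stem cells, had a scaled mean coverage of 1061 ± 162 in wild type and 1609 ± 289 in the knockout (SD, n = 3; log2 difference 0.59, SE 0.224; limma adjusted p = 0.597), and Zfp42 322 ± 49.8 and 331 ± 3.25. The list's camera test gave an adjusted p = 0.0126, and adjusted p = 0.572 with an estimated correlation. The list's median scaled coverage was 33.2, 27.4 and 28.2 in wild type replicates 1, 2 and 3. In the knockout it was above these in replicates 1 and 2 (at most 35.7) and below each of them in replicate 3 (26.3). Of the feeder fibroblast markers, 16 of 18 transcripts were lower in the knockout, with a median of -0.40, and 0 passed, over all transcripts or adjusted over the list alone (camera adjusted p = 0.00242, and adjusted p = 0.572 with an estimated correlation). Their median scaled coverage was 2.22, 3.29 and 6.97 in wild type replicates 1, 2 and 3 and 3.18, 3.29 and 2.91 in the knockout replicates, so wild type replicate 3 stood apart. Without both replicate 3 libraries the feeder median was -0.06 (camera adjusted p = 0.796, and adjusted p = 0.874 with an estimated correlation) and the pluripotency median 0.31 (camera adjusted p = 0.000208, and adjusted p = 0.404 with an estimated correlation). The 2 feeder markers with the highest coverage were Ccn2 at 58.7 ± 15.6 and 54.3 ± 9.86 and Fn1 at 33.1 ± 6.52 and 29.1 ± 6.69.

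For the remaining lists, 0 members passed over all transcripts, and camera gave adjusted p from 0.226 to 0.897. Of 8 early lineage transcripts, adjusted over the list alone, Lama1, a laminin chain of basement membranes, rose (3.38 ± 0.98 to 8.18 ± 1.82; log2 difference 1.17) and Sox1, a neural transcription factor, fell (3.42 ± 0.93 to 1.03 ± 0.28; log2 difference -1.34), at limma adjusted p of 0.015 and 0.0176 over the list and 0.366 over all transcripts for each. Sox1 lies on chromosome 8, whose transcripts had a median log2 difference of -0.51. Krt8 stood at 20.0 ± 13.6 and 29.2 ± 8.33 and Krt18 at 10.5 ± 5.97 and 14.4 ± 3.44. Of 11 RNA cytosine methylation genes, 1 passed when adjusted over the list alone, Trdmt1 itself (log2 difference -1.56, SE 0.363; limma adjusted p = 0.03 over the list, 0.366 over all transcripts). Alyref stood at 114 ± 15.2 and 104 ± 5.39 and Ybx1 at 87.1 ± 8.60 and 98.9 ± 15.6. Over the list alone 0 passed among 13 transcripts of the DNA methylation machinery (median -0.05; Tdg 31.1 ± 15.3 and 29.0 ± 13.8, Mbd3 20.9 ± 1.99 and 23.3 ± 2.42) and 26 of cytosolic aminoacyl-tRNA synthetases (median -0.01; Gars 140 ± 23.1 and 146 ± 6.37, Aars 136 ± 7.64 and 95.3 ± 7.76). The same held for 14 of the integrated stress response (median -0.14; Hspa5 137 ± 39.5 and 143 ± 48.9, Asns 96.5 ± 13.6 and 112 ± 10.9) and 12 of imprinted genes (median -0.16; Phlda2 61.8 ± 15.0 and 75.5 ± 17.6, Impact 41.7 ± 8.03 and 40.5 ± 4.28). Of the list of structural noncoding RNAs and that of mitochondrial transcripts, 0 members were measured among the mRNA references of the rRNA-depleted long fraction.

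Over all 10949 transcripts, 0 passed in limma, where 778 had an unadjusted p under 0.05. With library quality weights 4 passed (Foxd3 and Sgk1 higher, Lamp1 and Upf3a lower). Without knockout replicate 1, 1 passed, Cebpz, which has no listed cytosine in the other knockout libraries and entered the test there at a coverage of 0. In simulated data 25 of 100 changes of log2 1 and 68 of 100 of log2 2 were recovered. Among 174 tRNA genes 0 differed in coverage in limma (9 at an unadjusted p under 0.05; 6 with library quality weights).

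Transcripts of chromosome 8 genes sat lower in the knockout as a set, a feature chosen after the values were seen. Of 610 such transcripts 561 were lower, and their median log2 difference was -0.51, or -0.56 relative to the other chromosomes, whose own values ran from -0.01 to 0.07 over 19 chromosomes. Of the 444 transcripts lower at an unadjusted p under 0.05, 324 lay on chromosome 8, which held 5.60% of the transcripts. Rpl13, a ribosomal protein gene, had a scaled mean coverage of 2363 ± 261 in wild type and 1597 ± 44.9 in the knockout (SD, n = 3), and Klf2, a pluripotency factor, 162 ± 22.2 and 103 ± 11.1. Calr stood at 189 ± 18.5 and 157 ± 25.6, and Zfp42, also on chromosome 8, was not lower. Each of the 9 pairs of a wild-type and a knockout library gave a shift between -0.46 and -0.66, and 0 of 10000 random lists of 610 transcripts matched on mean coverage had a median as low (lowest -0.0005). The lists hold 5 aminoacyl-tRNA synthetase transcripts on this chromosome, Aars among them, 2 pluripotency transcripts (Klf2 and Zfp42), 2 of early lineages (Sox1 and Col4a1), 1 feeder marker (Mmp2) and 1 of the stress response (Herpud1).

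**Figure D4:**
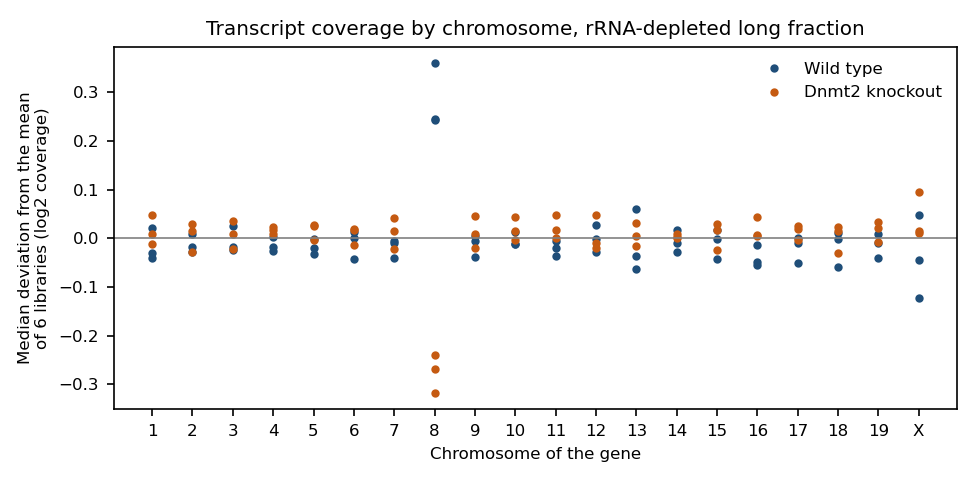
Median deviation of log2 transcript coverage from the mean of the 6 rRNA-depleted long libraries (vertical axis) for each chromosome (horizontal axis), 1 point per library, blue for wild type and orange for knockout. On chromosome 8 the wild-type libraries lie at 0.24 to 0.36 and the knockout libraries at -0.24 to -0.32.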

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

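The fits without both replicate 3 libraries, with library quality weights, without the unlisted transcripts and on cytosines covered in all 6 libraries were chosen after the results were seen; the other alternatives were planned. Of the alternative values of the main results, 99 stayed within 1.5 times, within the spread or in direction, 28 moved further and 3 turned direction; of named sites and transcripts, 16 values turned direction and 15 lost a call. Differing tRNA cytosines numbered 27 with the replicate block, 94 in Fisher's exact test and 33 without both replicate 3 libraries, each with all 14 of the calls; the last shows more calls with fewer libraries, and its cause was not tested. Single libraries left out gave 11 to 17. Differing mRNA cytosines numbered 27 in Fisher's exact test and 0 to 1 with a library left out. In the undepleted fraction 0 differed with the replicate block, 7 in Fisher's exact test and 0 at a mean non-conversion of 1% or more. Any library left out there leaves 1 library in an arm. The numbers were taken as only shared in that fraction. Its 2 libraries per genotype deviate from their mean by mirror values, so the correlation of 0.192 over 2 pairs is 1 value and cannot show pairing. Called mRNA cytosines depend on depth and the minimum: wild type 42 at coverage of 30, 48 at 20%, 216 to 357 with a library left out and 357 without both replicate 3 libraries; knockout 136, 129, 510 to 578, and 231 on cytosines covered in all 6. In the undepleted fraction 4 were called at 20% in either genotype, and 26 to 36 (wild type) and 27 to 31 (knockout) with a library left out. Transcripts differing in coverage numbered 0 to 1 with a library left out and 4 with quality weights, and tRNA genes 6 with quality weights. For transcript coverage the libraries share only a number (correlations 0.14, 0.041 and 0.303, 1 of them under 0.1), and the replicate block called 0. As for tRNA cytosines, not each library was highest with its own number. The block changed no other call beyond those given. The unweighted mean over gene copies at position 38 gave -66.2 percentage points. It gives each copy the same weight, including thin copies and copies of lower non-conversion in wild type. The background difference turned in the small fraction over all cytosines (-1.74 points, which includes the methylated ones) and ran from -0.0022 to 0.172 with a library left out, in the rRNA-depleted fraction from 0.0793 to 0.251, and in the undepleted fraction from -0.143 to 0.0206. Below the threshold in every fit, log2 coverage differences turned direction with a library left out for Ccn2 (-0.267 to 0.093), Gars (-0.041 to 0.187), Hspa5 (-0.225 to 0.22), Impact (-0.21 to 0.064), Tdg (-0.457 to 0.268) and Zfp42 (-0.076 to 0.16), without both replicate 3 libraries for Fn1 (0.137) and Hspa5 (-0.05), and with quality weights for Hspa5 (-0.126), Tdg (0.088) and Zfp42 (-0.022); the cause was not tested.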

Other observations

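The splits of the libraries, the tests of conversion, depth and the targeted transcript for position 38, the copy number value, all tests without both replicate 3 libraries, the search for unlisted transcripts and the sites named from Fisher's test and the replicate block were chosen after the results were seen. Clusters of non-converted cytosines were found in a few mRNAs. Of the called mRNA cytosines, 40 of 162 in wild type and 137 of 387 in the knockout lay within 10 nt of another. Fisher's exact test on summed counts, which ignores the spread between libraries, called clusters higher in the knockout in Ppp1r14b, an inhibitor of protein phosphatase 1, at position 322 (15.2 percentage points), Mybl2, a cell cycle transcription factor, at 132 (13.8 points) and Mycn at 718 (12.4 points), none of which passed in edgeR.

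With the replicate block, other cytosines of the same tRNA-Gly-CCC gene (chr3.trna752) were also lower in the knockout, at positions 46 (64.3% ± 4.72 to 51.3% ± 11.9, SD, n = 3; edgeR adjusted p = 7.64e-05 with the block and 0.353 without) and 48 (91.0% ± 1.33 to 84.6% ± 3.21; 2.04e-05 and 0.0764). The other cytosines that were lower only with the block were tRNA-Lys-TTT (chr11.trna1816) position 4, tRNA-Pro-CGG (chr11.trna396) positions 49, 48 and 47, tRNA-Ala-AGC (chr13.trna69) position 48, tRNA-Gly-TCC (chr11.trna1824) position 49 and tRNA-Gln-TTG (chr13.trna113) position 48, at -8.36, -7.85, -6.35, -5.68, -6.84, -5.84 and -4.84 points. Cytosines higher with the block were tRNA-Thr-CGT (chr13.trna75) position 73, tRNA-Tyr-GTA (chr14.trna191) position 65, tRNA-Ala-CGC (chr13.trna70) position 48 and tRNA-Leu-CAG (chr13.trna952) position 58, by 21.8, 15.8, 15.8 and 11.8 points. These calls are uncertain. In replicate 2, position 46 of tRNA-Gly-CCC stood at 64.2% in wild type and 63.3% in the knockout. Position 4 of tRNA-Lys-TTT rose there from 68.7% to 72.5%. With the block, edgeR adjusted p reached 9.46e-180 at position 38 of tRNA-Val-AAC (chr13.trna974), too small to measure the spread of 3 pairs of libraries. Beyond Hsp90ab1, transcripts with no listed cytosine in single libraries were Nacc1 and Ccdc59 (wild type replicate 2), Mtrex and Mief1 (knockout replicate 2), Nup205, Crls1, Mtg1, Trappc1 and Ttll4 (knockout replicate 3) and Cebpz (knockout replicates 2 and 3).

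The fall at position 38 was set against 2 technical explanations. More complete conversion in the knockout libraries would lower the background, which was 1.89% in wild type and 1.97% in the knockout. The 179 other tRNA cytosines called in wild type had a median difference of -0.029 points (quartiles -2.41 and 2.16). That median cannot decide, since methylated cytosines stay unconverted however complete the conversion is. Fewer reads are argued against by a lowest pooled knockout coverage of 3538 reads. The targeted transcript, read in the rRNA-depleted long libraries, had 0 listed cytosines from position 200 in every knockout library and at least 48 in wild type. The absence of Dnmt2 may thus account for the fall seen in the small libraries. The comparison at position 38 was fixed in advance. The check of the transcript from position 200 was chosen after the values were seen, so the link between the 2 stays a hypothesis. Of the 10 splits of the 6 libraries, 1, the real one, gave as many as 14 cytosines and the highest other gave 0; 10 splits are too few for a share under 0.05.

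The lower coverage of chromosome 8 transcripts does not rest on 1 library, since the shift was -0.51 or lower without each. It is not set by coverage level, with a median of -0.51 against -0.0005 for the lowest of 10000 matched random lists, nor by a part of the chromosome, since the highest of 4 equal parts in gene order lay at -0.55. A difference in chromosome copy number between the wild-type and knockout cells may account for it: the shift of -0.56 lies near log2 of 2 copies against 3 (-0.58), but 3 against 4 (-0.42) or a mixture of cells is not excluded. Which genotype carries the change was not settled, and genes of a chromosome are not independent replicates.

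More mRNA cytosines were called in the knockout, 387 against 162. With every cytosine thinned to 10 reads in all 6 libraries the counts were 139 and 109, a ratio of 1.27, so depth of coverage may account for part of the gap. Thinning also loses calls in both genotypes. Without both replicate 3 libraries similar numbers of cytosines were tested (1544230 in the knockout, 1489020 in wild type), and the knockout count stayed higher (578 and 357). Local failure of conversion stays open: uncalled cytosines within 10 nt of called ones had medians of 1.13 (wild type) and 1.28 (knockout) times the background, but this leaves out called neighbours, and 24.7% and 35.4% of the calls had one. Replicate 3 as the only source is argued against by a ratio of 1.62 without both such libraries (578 and 357), though the ratio was 2.39 with them. The knockout libraries left then had backgrounds of 1.77% and 1.76%, against 1.59% and 1.45% in wild type. Whether this difference in background adds to the gap was not tested. What remains of the gap at equal depth stays open, as does a ratio of 1.46 at the cytosines covered in all 6 libraries (231 and 158).

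For differing mRNA cytosines and for transcript and tRNA gene coverage the real count was 0, so 10 of 10 splits give as many by construction and the share says nothing about chance. The highest other split called 9 mRNA cytosines, and 0 in coverage. Each split with both replicate 3 libraries on the same side called 8 or 9 mRNA cytosines, and each of the others called 0. This points to a structure of the samples other than genotype, which goes with replicate 3.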
